A study of Capsella grandiflora and Capsella rubella and Capsella orientalis with 27 samples.

How the data were processed

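Messenger RNA levels were measured by RNA sequencing in 3 species of Capsella, a genus of the mustard family: C. grandiflora, an outcrossing species, and C. rubella and C. orientalis, which fertilise themselves. Each species was sampled at 3 stages: expanding and maturing flower buds, dividing flower buds, and seedlings 10 days old. Each of the 9 groups held 3 libraries, 27 in all. Per the labels' protocols, total RNA was extracted with a plant RNeasy kit, TruSeq RNA libraries were made, and single reads of 50 cycles were sequenced on a HiSeq2000 instrument.

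The deposited files hold raw read counts per gene, 1 file per library, which the authors made with HTSeq after trimming with Trimmomatic, per the submitters' processing notes. Tool versions, the aligner, the genome build, the annotation and the strand setting are not given in the sources used here. All 27 files list the same 26521 gene identifiers, so reads of the 3 species were assigned to a single set of gene models. The identifiers start with Carubv, the form of C. rubella gene models, though the genome used is not stated. Reads of a species that differ in sequence from those models can be lost or assigned elsewhere, and such an effect changes a gene's count in that species at every stage. With C. rubella models such losses may be fewer in C. rubella than in the other species, which was not tested. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and near-identical copies of a gene can share or lose reads.

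The files also hold 5 summary rows that name no gene, and these were left out of library sizes and tests. As group means, reads outside any gene made up 3.04% to 5.57% of all listed reads, ambiguous reads 3.78% to 4.63% and reads that aligned to several places 4.13% to 9.30%. The rows for unaligned and low-quality reads were 0 in every library, so the share of reads that aligned is unknown.

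The files do not pair the identifiers with gene names, and no annotation was used here. Of 32 gene lists fixed before the data were examined as patterns on gene names, 0 matched any identifier, so the planned tests of those lists were not run. Genes were instead grouped by their own stage profile, a choice made after it was seen that the identifiers carry no names. A gene was called preferential to a stage of a species when it was called and at least 2-fold higher there than at each of the other stages of that species. Genes preferential to both bud stages were called and at least 2-fold above seedlings in each and were not 2-fold apart with a call between the bud stages. Even genes had fitted folds under 2-fold between all stages. For a comparison of a pair of species the groups were taken from the third species alone, so that the libraries compared did not choose the genes. Shares of reads, as percent of the counts on tested genes, were computed for genes that met the rule in all 3 species.

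Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 23186 genes, and libraries were scaled by the trimmed mean of M-values (TMM). All 27 libraries entered a single fit of 9 group means with 18 residual degrees of freedom, and contrasts were tested with edgeR's quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 folds were obtained as the fold divided by the square root of the F value. Where a group held only a few counts, such a standard error can be too small to cover counting error. Levels are given as CPM, counts scaled to a common library size with TMM factors, as mean ± SD over 3 libraries. Stage groups were tested with limma 3.58.1, by camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 45 tests. Shares of reads were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

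Gene counts per library ranged from 10612848 to 40909319, with the lowest depth in C. grandiflora seedlings. The labels do not say whether the replicates of a group came from separate plants. The p-values therefore measure the spread between these samples, which may be technical. A chi-square over genes with at least 20 counts gave 5.14 to 43.0 per degree of freedom for replicate pairs, so that no pair agreed within sampling noise and all 27 libraries were counted. The common biological coefficient of variation was 0.111. In simulated counts for C. rubella against C. grandiflora expanding buds, with 23186 genes of which 200 were changed, 40.3% of 1.5-fold, 73.1% of 2-fold and 92.4% of 4-fold changes were called, and 1 of 22986 unchanged genes. The same test in seedlings gave 44.8%, 71.6% and 86.4%, and 27 of 22986 unchanged genes. The real expanding bud comparison called 13830 genes. The adjusted p cut is looser where more genes differ, so neither the simulated recovery nor the simulated false calls carry over to the real comparisons.

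A rule fixed before the data were examined allows at most 2 higher and 2 lower identifiers per contrast where identifiers carry no names. For each stage the 2 highest and 2 lowest genes called in both selfing species were named, ranked by the smaller of the absolute log2 folds. Each species contrast added 1 higher and 1 lower gene by log2 fold, each stage contrast 1 of each called in all species, and each interaction the gene with the lowest p. The 2 genes with the highest counts elsewhere were named among those without counts in a species. Apart from the interactions and the genes without counts, a named gene had a mean log2 CPM of at least 1, more than 3 counts in the lower group and no overlap between the libraries compared.

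Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, an adjusted p under 0.01, a log2 fold of at least 1, fits of the compared groups only, removal of genes at 0 in a species, a replicate block and leaving out each library. Thinning of every library to the lowest depth, other set tests and a 4-fold preference were added after seeing the data. C. rubella and C. orientalis were each compared with the same C. grandiflora libraries, so chance values were also taken from 20 simulated data sets in which every library was drawn from the C. grandiflora means of its stage. Counts of 3 per group were too few to split the C. grandiflora libraries into separate sets of at least 2.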

Results

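RNA from flower buds and seedlings of 3 Capsella species was compared to ask whether the species that evolved self-fertilisation separately, C. rubella and C. orientalis, share changes in gene activity relative to the outcrossing C. grandiflora. Selfing lineages often carry small flowers with little pollen, a set of traits called the selfing syndrome. Gene counts per library averaged 32.1 ± 7.62 M in C. grandiflora expanding buds, 35.1 ± 3.92 M in C. rubella and 30.003 ± 3.23 M in C. orientalis (SD, n = 3 each). In dividing buds the means were 35.5 ± 3.86, 28.1 ± 6.63 and 27.2 ± 1.79 M in the same order, and in seedlings 16.5 ± 5.66, 25.4 ± 1.01 and 24.6 ± 5.08 M. The first principal component held 46.3% of the variance and separated buds from seedlings, and the second, with 23.5%, separated the bud stages. The next component held 13.3% and set C. orientalis apart from the other species.

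**Figure D1:**
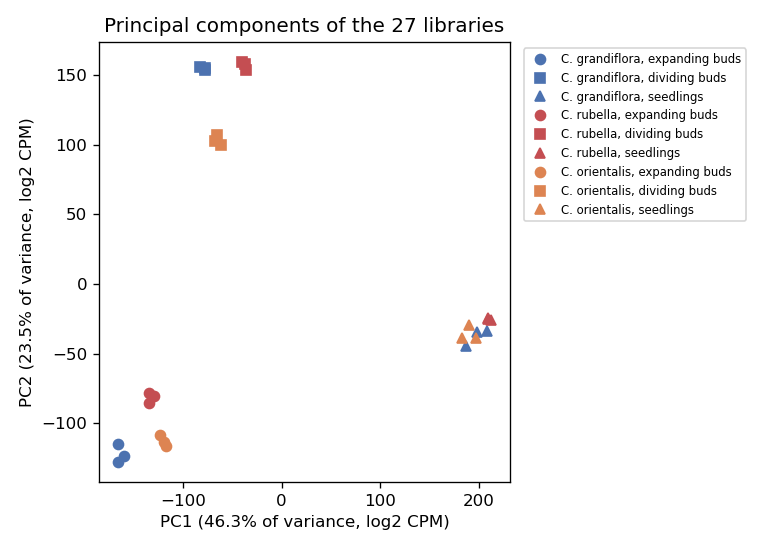
Each point is a library, placed by its first (x axis) and second (y axis) principal component of log2 CPM. Stages, shown by marker shape, form 3 clusters, and species, shown by colour, separate within each bud stage.

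In expanding buds, genes typical of that stage were lower in both selfing species than in C. grandiflora. Of 2070 genes preferential to expanding buds in C. orientalis, 1385 were lower and 253 higher in C. rubella, with a median log2 fold of -0.71. The set stood below the other genes by camera (Benjamini-Hochberg adjusted p = 2.77e-09, and adjusted p = 0.0029 with an estimated correlation). Of 2488 genes preferential to expanding buds in C. rubella, 1559 were lower and 319 higher in C. orientalis than in C. grandiflora, with a median log2 fold of -0.75. Camera gave a Benjamini-Hochberg adjusted p = 2.25e-07, and adjusted p = 0.0201 with an estimated correlation. Genes preferential to both bud stages were lower in C. orientalis, with 848 lower and 416 higher of 1814 (camera, Benjamini-Hochberg adjusted p = 0.0197, but adjusted p = 0.381 with an estimated correlation). Even genes, 9898 in number, stood above the rest in C. orientalis by camera (Benjamini-Hochberg adjusted p = 0.0244, and adjusted p = 0.0404 with an estimated correlation). Of them 4038 were higher and 2910 lower, and their median log2 fold was 0.10 while their mean was slightly negative, at -0.0028.

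Over all genes in expanding buds, edgeR's quasi-likelihood test called 13830 of 23186 genes between C. rubella and C. grandiflora, 6998 of them higher and 6832 lower in C. rubella. In C. orientalis 15713 were called, 7574 higher and 8139 lower. The balance of directions depends on scaling: with RLE size factors 6147 were higher and 7713 lower in C. rubella, and 6876 and 8807 in C. orientalis. At least 2-fold, 2128 were higher and 2588 lower in C. rubella, and 2357 were higher and 3988 lower in C. orientalis. Among single identifiers, Carubv10025295m.g stood at 120 ± 18.2 CPM in C. rubella and at 0.0382 ± 0.0389 CPM in C. grandiflora, while Carubv10028157m.g was at 0.0371 ± 0.0183 against 75.1 ± 4.58 CPM. Carubv10003549m.g had a log2 fold of 8.87 (SE 0.28) in C. orientalis, and Carubv10013138m.g one of -10.67 (SE 0.25), with edgeR's quasi-likelihood Benjamini-Hochberg adjusted p = 2.26e-18 and 1.34e-20. Their lower groups held 8 counts (C. grandiflora) and 4 counts (C. orientalis), so these SEs are too small to cover counting error.

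In dividing buds it was the genes typical of dividing buds that were lower. Of 1587 genes preferential to dividing buds in C. orientalis, 1064 were lower and 206 higher in C. rubella than in C. grandiflora, and 904 were lower by at least 2-fold. Their median log2 fold was -1.27 (camera, Benjamini-Hochberg adjusted p = 5.27e-13, and adjusted p = 0.0404 with an estimated correlation). In C. orientalis, 916 of 1399 genes preferential to dividing buds in C. rubella were lower and 166 higher. The median log2 fold was -1.16 (camera, Benjamini-Hochberg adjusted p = 3.27e-13, and adjusted p = 0.0201 with an estimated correlation). Genes preferential to both bud stages were lower in both species by camera, with 659 of 1513 lower in C. rubella and 801 of 1814 lower in C. orientalis. Their Benjamini-Hochberg adjusted p was 0.0064 and 0.00373, but those calls were lost with an estimated correlation (adjusted p = 0.0937 and 0.282). In C. rubella the 2070 expanding-preferential genes were lower too, 708 lower and 230 higher (camera, Benjamini-Hochberg adjusted p = 0.00736, but adjusted p = 0.0937 with an estimated correlation). The 10410 even genes stood slightly above the rest in C. rubella, at a median log2 fold of 0.04 (camera, Benjamini-Hochberg adjusted p = 0.0447, but adjusted p = 0.0541 with an estimated correlation).

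edgeR's quasi-likelihood test called 11982 genes in dividing buds of C. rubella against C. grandiflora, 5569 higher and 6413 lower, and 13759 in C. orientalis, 6975 higher and 6784 lower. The larger direction in C. orientalis turned with RLE size factors (6235 higher and 7370 lower), DESeq2 (6448 and 7546) and a fit of the compared groups alone (6797 and 7448). The balance was more uneven among 2-fold differences, with 1508 higher and 3391 lower in C. rubella and 2186 higher and 3400 lower in C. orientalis. Carubv10025718m.g stood at 101 ± 5.996 CPM in C. rubella and 0.0311 ± 0.00997 CPM in C. grandiflora, and Carubv10027327m.g at 0.0681 ± 0.0625 against 28.4 ± 1.81 CPM. In C. orientalis the corresponding genes were Carubv10026015m.g, with a log2 fold of 10.17 (SE 0.22), and Carubv10023978m.g, with -9.92 (SE 0.22). Carubv10023978m.g was at 164 ± 5.71 CPM in C. grandiflora, 153 ± 1.38 CPM in C. rubella and 0.166 ± 0.0428 CPM in C. orientalis.

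In seedlings, none of the 15 camera tests of stage groups passed at an adjusted p under 0.05. At an unadjusted p under 0.05 camera gave 1 set. The fry test, which asks only whether a set moves, called 8 at a Benjamini-Hochberg adjusted p under 0.05. edgeR's quasi-likelihood test called 9995 genes between C. rubella and C. grandiflora seedlings, 4671 higher and 5324 lower, and 12934 between C. orientalis and C. grandiflora, 6429 higher and 6505 lower. At least 2-fold, 1384 were higher and 2060 lower in C. rubella, and 1856 were higher and 3187 lower in C. orientalis. Carubv10001442m.g stood at 100.2 ± 8.28 CPM in C. rubella against 0.147 ± 0.142 CPM in C. grandiflora, and Carubv10001198m.g at 0.0809 ± 0.140 against 119 ± 10.1 CPM. Carubv10021136m.g had a log2 fold of 11.48 (SE 0.35) in C. orientalis and Carubv10024623m.g one of -10.08 (SE 0.23). A fit of the compared seedling groups alone called 5861 genes for C. rubella. The C. grandiflora seedling group had the lowest mean depth, with libraries of 10612848 to 21880641 counts.

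Of the genes called in both selfing species against C. grandiflora, most differed the same way, above all in expanding buds. There, 4032 genes were higher and 4349 lower in both, 8381 in all, and 1958 were called in opposite directions, so that 81.1% of genes called in both comparisons had the same sign. In dividing buds 2609 were higher and 3335 lower in both, against 2226 opposite (72.8% the same), and in seedlings 1688 and 2285 against 2461 (61.8%). Leaving out any of the 9 libraries of a stage gave shares of 81.2% to 82.9%, 73.1% to 74.8% and 59.8% to 64.2%. The full shares of both bud stages lay below these ranges, so the ranges do not measure sampling spread. The difference between stages was not tested. Many genes were called in a single selfing species: 3491 in C. rubella and 5374 in C. orientalis in expanding buds, 3812 and 5589 in dividing buds, and 3561 and 6500 in seedlings. At least 2-fold in both, 737 genes were higher and 1435 lower in expanding buds, 500 and 1650 in dividing buds, and 342 and 966 in seedlings. Among same-way genes in expanding buds that were also called between the bud stages, most followed the bud stages. Of 4319 called alike between bud stages in all 3 species, 3822 (88.5%) were lower where expanding buds are higher or higher where dividing buds are higher, and 85.1% of 4549 when the selfing species alone set the direction. Over all genes the relation was weak, with correlations of -0.128 in C. rubella and -0.107 in C. orientalis between the species fold and the bud stage fold of the other selfing species. Same-way genes in seedlings numbered 2600 at an adjusted p under 0.01 and 2514 in a fit of the seedling groups alone.

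**Figure D2:**
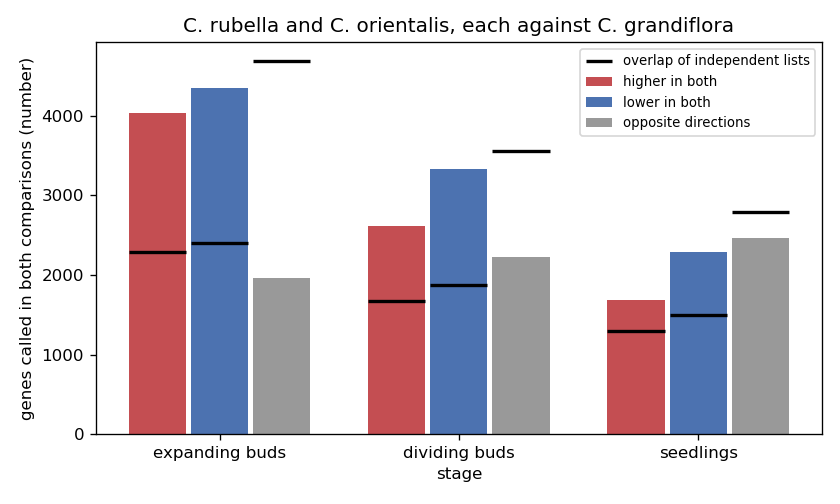
Bars give the number of genes called by edgeR's quasi-likelihood test in both C. rubella and C. orientalis against C. grandiflora (y axis) at each stage (x axis), by direction, and black lines give the overlap of independent lists of the same sizes. Genes higher or lower in both lie above the lines and genes in opposite directions below them, at 1958 in expanding buds, 2226 in dividing buds and 2461 in seedlings.

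Both comparisons used the same C. grandiflora libraries. Independent lists would share 4684 same-way genes in expanding buds, 3552 in dividing buds and 2789 in seedlings. In 20 simulated data sets every library, those of C. grandiflora included, was drawn from the C. grandiflora means with the spread between replicates. The replicate noise of the shared libraries thus entered both comparisons, but no deviation common to all libraries of a group did. The simulated data sets called at most 3 genes in either comparison, so their same-way counts of at most 1 say little. The covariance of the log2 folds across genes was 0.927, 0.867 and 0.673 for the stages in the same order, and its highest simulated values were 0.0794, 0.0700 and 0.141. The correlation across genes, which are not independent replicates, was 0.338, 0.310 and 0.268, below the simulated medians of 0.515, 0.434 and 0.589, since shared noise alone gives such values. The correlation is therefore no measure of a shared change. No outgroup was sequenced among these samples, so a shared difference does not say whether the selfing species or C. grandiflora changed. A change in C. grandiflora alone enters both comparisons with the same sign.

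Of the genes higher in both selfing species, Carubv10021533m.g met the naming rule at all 3 stages. It stood at 0.318 ± 0.0638 CPM in C. grandiflora expanding buds, 60.2 ± 3.47 CPM in C. rubella and 71.99 ± 5.60 CPM in C. orientalis, with log2 folds of 7.55 (SE 0.21) and 7.81 (SE 0.21). In seedlings its log2 folds were 9.64 and 9.86. Carubv10026225m.g was the other named gene in expanding buds, at 32.4 ± 0.513 and 13.3 ± 0.780 CPM in C. rubella and C. orientalis against 0.0496 ± 0.0561 CPM. Carubv10022713m.g in dividing buds had log2 folds of 9.20 and 9.14, and Carubv10002575m.g in seedlings 7.55 and 7.10. Among genes lower in both, Carubv10027515m.g was at 46.3 ± 3.18 CPM in C. grandiflora expanding buds, with log2 folds of -10.15 and -8.80, and Carubv10028503m.g had -8.48 and -6.41. In dividing buds Carubv10028365m.g had -8.03 and -6.57 and Carubv10026535m.g -6.29 and -7.17. In seedlings Carubv10013351m.g had -7.04 and -7.26, and Carubv10009713m.g -8.71 and -6.27. The highest adjusted p among these was 6.83e-07, for Carubv10009713m.g in C. orientalis (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). Such near-complete differences are also what a gene model that fits only some of the species would give.

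The genes preferential to a bud stage in all 3 species took a smaller part of the reads in the selfing species. The 1468 expanding-preferential genes held 15.99% ± 0.610 of counts on tested genes in C. grandiflora expanding buds, 9.05% ± 0.190 in C. rubella and 9.84% ± 0.148 in C. orientalis (SD, n = 3 each). The 836 dividing-preferential genes held 3.98% ± 0.344, 2.04% ± 0.0704 and 1.99% ± 0.0957 in dividing buds. No library of a selfing species overlapped those of C. grandiflora in either measure (exact permutation p = 0.1, the smallest possible), and 10% of comparisons of 3 with 3 would show no overlap by chance. In expanding buds 786 of the 1468 genes (53.5%) were lower in both selfing species and 66 higher in both. In dividing buds 556 of the 836 (66.5%) were lower in both and 26 higher in both. The summed share of the 2271 seedling-preferential genes was larger in buds of the selfing species, with 5.16% ± 0.267, 8.02% ± 0.0925 and 7.04% ± 0.300 of counts in expanding buds and 5.57% ± 0.336, 7.51% ± 0.225 and 6.93% ± 0.0950 in dividing buds. In seedlings, their own stage, they held 28.6% ± 1.65, 31.6% ± 0.584 and 33.1% ± 0.460, larger in both selfing species without overlap (exact permutation p = 0.1). Gene by gene, seedlings showed no excess of higher genes, with 247 higher and 303 lower in both selfing species, a balance that was not tested. In C. orientalis seedlings 957 of 3682 genes preferential to seedlings in C. rubella were higher and 1465 lower, with a median log2 fold of -0.22 (fry, Benjamini-Hochberg adjusted p = 1.15e-06, but camera, adjusted p = 0.1). In C. rubella seedlings neither test called the 3704 genes preferential to seedlings in C. orientalis. Of them 902 were higher and 961 lower, with a median of -0.02 (Benjamini-Hochberg adjusted p = 0.833 by camera and 0.379 by fry). Of the 2271 seedling-preferential genes 17.4% were higher in both selfing species in expanding buds, against 19.9% of even genes, and 14.8% against 12.3% in dividing buds. The difference between the bud stages was not tested. No camera test of seedling-preferential genes against C. grandiflora was called in buds (lowest Benjamini-Hochberg adjusted p = 0.0545). The 379 genes of both bud stages held 2.58% ± 0.0811 in C. grandiflora expanding buds, 2.84% ± 0.00653 in C. rubella and 2.47% ± 0.0984 in C. orientalis. In dividing buds they held 3.08% ± 0.0860, 2.79% ± 0.0938 and 2.55% ± 0.0718, lower in both selfing species without overlap (exact permutation p = 0.1, the smallest possible).

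**Figure D3:**
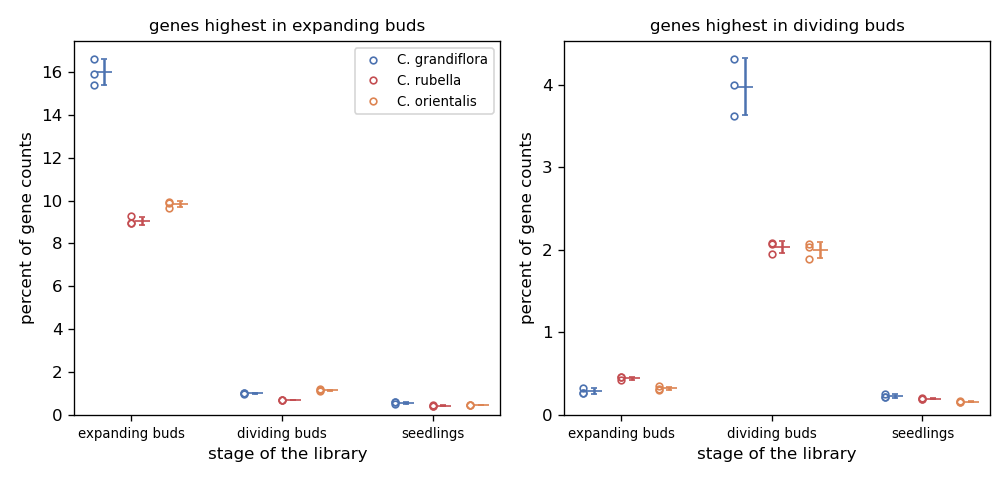
Open circles are libraries and bars are means with SD (n = 3), showing the percent of gene counts (y axis) on expanding-preferential (left) and dividing-preferential (right) genes at each stage (x axis). At their own stage the shares are 15.99%, 9.05% and 9.84% on the left and 3.98%, 2.04% and 1.99% on the right for C. grandiflora, C. rubella and C. orientalis.

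In buds a direct comparison of the selfing species gave smaller differences for genes of the sampled stage, and camera called none. In seedlings the median log2 fold of seedling-preferential genes was -0.09, against -0.02 in C. rubella and -0.22 in C. orientalis compared with C. grandiflora. With groups taken from C. grandiflora, 790 of 2730 expanding-preferential genes were higher and 870 lower in C. orientalis than in C. rubella expanding buds, with a median log2 fold of 0.01 (camera, Benjamini-Hochberg adjusted p = 0.883). Of 1996 dividing-preferential genes in dividing buds 515 were higher and 712 lower, with a median of -0.15 (camera, Benjamini-Hochberg adjusted p = 0.144). The fry test, which asks only whether a set moves, called both sets lower in C. orientalis (Benjamini-Hochberg adjusted p = 0.00109 and 0.0107). The expanding-preferential share of reads went the other way, at 9.84% in C. orientalis against 9.05% in C. rubella without overlap (exact permutation p = 0.1), and the dividing-preferential shares overlapped. Genes of the other bud stage also differed by camera. In dividing buds 1200 of the 2730 expanding-preferential genes were higher in C. orientalis and 451 lower (camera, Benjamini-Hochberg adjusted p = 0.00166, but adjusted p = 0.0937 with an estimated correlation). In expanding buds 825 of 1996 dividing-preferential genes were lower and 385 higher (camera, Benjamini-Hochberg adjusted p = 0.0447, but adjusted p = 0.507 with an estimated correlation).

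Over all genes, edgeR's quasi-likelihood test called 14410 between C. orientalis and C. rubella in expanding buds (6854 higher and 7556 lower in C. orientalis), 13584 in dividing buds (7213 and 6371, but 7143 and 7372 when only the compared groups were fitted) and 13963 in seedlings (7287 and 6676). At least 2-fold the counts were 5667, 5799 and 5824. Carubv10025295m.g was the named lower gene in both bud stages, with log2 folds of -11.28 (SE 0.31) and -11.11 (SE 0.29). Carubv10001198m.g in expanding buds and Carubv10002233m.g in dividing buds were higher, with log2 folds of 9.92 and 10.58. In seedlings Carubv10021136m.g had 12.62 and Carubv10026457m.g -11.12. As root mean square differences of group means, with replicate noise removed, C. rubella lay 1.101, 1.15 and 0.989 log2 units from C. grandiflora in expanding buds, dividing buds and seedlings. C. orientalis lay 1.34, 1.30 and 1.23 from C. grandiflora and 1.39, 1.44 and 1.42 from C. rubella.

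Expression changed between the bud stages of every species, and the change was widest in C. grandiflora. The root mean square difference was 1.95 log2 units in C. grandiflora, 1.76 in C. rubella and 1.59 in C. orientalis, and leaving out any library kept these within 1.93 to 1.97, 1.74 to 1.77 and 1.58 to 1.60. edgeR's quasi-likelihood test called 16702, 14902 and 13684 genes in that order, and 4938 were higher and 4633 lower in expanding buds of all 3 species. Carubv10015454m.g was at 358 ± 13.8, 186 ± 11.04 and 285 ± 41.5 CPM in expanding buds of C. grandiflora, C. rubella and C. orientalis and at 0.261 ± 0.184, 0.112 ± 0.0375 and 0.309 ± 0.208 CPM in dividing buds. Carubv10006531m.g was lower in expanding buds, with log2 folds of -7.43, -7.59 and -8.72. Across genes the log2 folds of C. rubella and C. orientalis had slopes of 0.809 and 0.693 on those of C. grandiflora. The reverse slopes, 0.926 and 0.904, were below 1 too, so slopes under 1 do not rank the species.

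Between dividing buds and seedlings 17809, 17689 and 17222 genes were called in C. grandiflora, C. rubella and C. orientalis, and 6446 were higher and 5645 lower in dividing buds of all 3. Carubv10021677m.g stood at 888 ± 151, 359 ± 27.9 and 421 ± 31.6 CPM in dividing buds and at a mean below 1 CPM in seedlings of each species. Carubv10014831m.g was its counterpart in seedlings, at 745 ± 77.3, 991 ± 103.97 and 299 ± 22.5 CPM, with log2 folds of -13.81, -14.12 and -11.22 for dividing buds against seedlings.

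The difference between a selfing species and C. grandiflora itself differed between stages for many genes. By edgeR's quasi-likelihood test of the interaction, 5330 genes differed between expanding and dividing buds for C. rubella and 8050 for C. orientalis. Between dividing buds and seedlings the counts were 7158 and 7804. At an adjusted p under 0.01 the counts were 3086 and 5208 for the bud stages and 4720 for C. rubella between dividing buds and seedlings. For C. orientalis between bud stages, 48.5% of called genes had a positive interaction, and 59.4% of the 9380 called when only the compared groups were fitted and scaled. Carubv10025640m.g had the lowest p for the bud stages in both species. It was at 35.7 ± 4.41 CPM in C. grandiflora expanding buds but had 1 count in all its dividing bud libraries, whereas C. rubella stood at 39.2 ± 0.910 and 31.8 ± 1.88 CPM and C. orientalis at 58.3 ± 7.09 and 37.1 ± 1.38 CPM. In dividing buds its ratio of C. rubella to C. grandiflora was 3973, with an exact 95% counting interval from 713 to 156971. Carubv10009981m.g was 23.0 times as high in C. rubella as in C. grandiflora dividing buds and 0.695 times as high in seedlings. Carubv10006008m.g was 3.77 times as high in C. orientalis as in C. grandiflora dividing buds and 0.00409 times as high in seedlings.

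Some genes had no counts in a species. Of 26521 identifiers 923 were at 0 in all 27 libraries. A further 402 had no count in the 9 libraries of C. grandiflora, 605 in C. rubella and 1022 in C. orientalis, and with all libraries thinned to 10612848 counts these were 551, 813 and 1210. Carubv10019632m.g had 0 counts in C. grandiflora and was at least 430-fold higher in C. rubella and at least 213-fold higher in C. orientalis, against a floor of 3 counts over 9 libraries. Carubv10022460m.g had none in C. rubella and 1 count in C. orientalis and was at least 1301-fold higher in C. grandiflora than in C. rubella. Carubv10004951m.g had none in C. orientalis and was at least 548-fold higher in C. grandiflora and 683-fold in C. rubella. Carubv10007947m.g, at 0 in C. grandiflora, was at least 609-fold higher in C. rubella and had 1 count in C. orientalis, and Carubv10022333m.g, at 0 in C. rubella, was at least 1142-fold higher in C. orientalis and at least 9.12-fold higher in C. grandiflora, with 26 counts. Carubv10001216m.g had none in C. orientalis and was at least 313-fold higher in C. grandiflora and 826-fold in C. rubella. These floors cover counting error only. A gene at 0 may lack transcripts or lack reads that match the gene model, which the counts do not tell apart.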

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

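The tests on the share of reads of stage-preferential genes, the test of a shift between the bud stages, the redrawing of C. grandiflora libraries in the simulations and the count by fold alone were chosen after the results were seen, and the other tests in this part before. The first pattern is the same-way difference of 8381 genes in expanding buds. Replicate noise of the shared C. grandiflora libraries does not account for it. The covariance of log2 folds was 0.927, and at most 0.0794 in 20 simulated data sets. A deviation common to all C. grandiflora libraries of a stage was not simulated and stays open. An alignment or annotation effect fixed per gene would recur in seedlings. Of 6382 same-way genes expressed there 19.9% were called in seedlings in their own direction. Of all 23186 tested genes, expressed there or not, 1688 were higher and 2285 lower in both species in seedlings. Their joint share of 17.1% counts either direction, so it is no matched base and does not show whether same-way genes recur more often. A gene uncalled in seedlings, where depth was lower, can still carry such an effect, so the 19.9% does not decide the question. A different mix of bud ages cannot be told apart. Of 4319 same-way genes called alike between the bud stages in all 3 species, 88.5% lay on the side that a shift toward dividing buds gives. That share lies between the bounds of 75% and 90% set for either outcome. With any of 18 bud libraries left out it ran from 88.1% to 90.2%, so its highest value passed the upper bound. The 71.3% of equal signs among 935 genes without a call between bud stages decides nothing, since the shared C. grandiflora reference alone raises it. A shared species difference from C. grandiflora, its lineage of origin and growing conditions stay open and untested.

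The second pattern is the set of 1650 genes at least 2-fold lower in both selfing species in dividing buds. Replicate noise of the shared libraries does not account for it. In 20 simulated data sets at most 128 genes were 2-fold lower in both by fold alone, without a call. A deviation common to all C. grandiflora libraries of the stage was not simulated here either. More RNA of older buds in the C. grandiflora libraries would raise genes of expanding buds, but 19.7% of the set were called higher in expanding than in dividing buds of C. grandiflora, against 35.9% of all tested genes, while 58.7% were called higher in dividing buds, against 36.1%. The set was chosen for high levels in the same C. grandiflora dividing bud libraries, which by itself raises the share higher in dividing buds. The gap to all tested genes is therefore partly built in. Of the 487 members expressed in expanding buds, 66.3% were also lower in both species there. An effect of alignment fixed per gene cannot be told apart from expression for such members, because that share lies between the values set for either outcome and no genome of each species was used.

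The third pattern is the smaller share of reads on genes preferential to a bud stage at that stage in both selfing species. Even dilution by other tissue would lower the genes of both bud stages by a like factor. The ratios to C. grandiflora instead differed by at least 0.326 in both species and at both stages. This covers an even dilution only. An uneven difference in the tissue make-up of the buds was not tested and stays open. A few abundant genes do not carry it, since without the 10 most abundant members the ratio to C. grandiflora was at most 0.672. Bud age at harvest may contribute and cannot be told apart from a species difference, since the labels give no bud size or age. Genes of the other bud stage had ratios of 1.53 in C. rubella and 1.11, with overlapping libraries, in C. orientalis in expanding buds, the direction of a bud age difference, and of 0.678 and 1.14 in dividing buds, where only C. orientalis goes that way.

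The interaction counts, which mark genes whose species difference changed with stage, were 5330 for C. rubella between the bud stages, 7158 for C. rubella between dividing buds and seedlings, 8050 for C. orientalis between the bud stages and 7804 for C. orientalis between dividing buds and seedlings. The genes with the lowest p had log2 interactions of -11.20 and -10.85 (Carubv10025640m.g, in C. rubella and C. orientalis), 5.02 (Carubv10009981m.g) and 9.80 (Carubv10006008m.g). The values of Carubv10025640m.g depend on the prior count, since C. grandiflora dividing buds held 1 count.

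In rows that name no gene, every library of a selfing species lay above every C. grandiflora library of the same stage in 6 cases, below in 10 and overlapping in 2. Reads outside any gene were 5.53% in C. rubella expanding buds against 5.25% in C. grandiflora, 5.57% against 4.65% in dividing buds and 4.84% against 4.31% in seedlings. Ambiguous reads were 4.198% in C. orientalis seedlings against 3.89%. Reads with several alignments were 6.75% in C. orientalis expanding buds against 4.33% and 7.90% against 4.97% in dividing buds. Below C. grandiflora lay reads outside genes in C. orientalis at all 3 stages (3.93%, 4.11% and 3.04%) and reads with several alignments in C. rubella at all 3 stages (4.13%, 4.45% and 7.10%) and in C. orientalis seedlings (8.33%, against 9.30%). Ambiguous reads lay below in dividing buds of both and in C. orientalis expanding buds.

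Other splits of the libraries were fitted to ask how often edgeR's quasi-likelihood test gives as many genes. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each of the 15 comparisons 1 split, the real one, gave as many. For C. rubella against C. grandiflora the real counts and the highest other split were 13830 and 0 in expanding buds, 11982 and 10 in dividing buds and 9995 and 1954 in seedlings. For C. orientalis against C. grandiflora they were 15713 and 0, 13759 and 0, and 12934 and 65. For C. orientalis against C. rubella they were 14410 and 0, 13584 and 0, and 13963 and 5. For expanding against dividing buds they were 16702, 14902 and 13684 against 0 in each species, and for dividing buds against seedlings 17809 and 10, 17689 and 0, and 17222 and 0 in C. grandiflora, C. rubella and C. orientalis.

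For same-way genes, 1 of 22 drawn splits, the real one, gave as many at each stage. The real split is always among the 22, so no smaller share was possible. A split that puts different species in a group widens its spread and calls few genes, whether or not the selfing species share changes. These splits therefore do not test a shared change. The real counts and the highest other split were 8381 and 0, 5944 and 0, and 3973 and 90 for expanding buds, dividing buds and seedlings. For the interactions this count cannot decide on chance regrouping. A split that keeps the libraries of a species together in a stage carries the species difference itself. As many genes as the real split were given by 4 of 22 splits for C. rubella between bud stages (5330, highest other 14765) and by 3 of 22 between dividing buds and seedlings (7158, highest other 11919). For C. orientalis it was 4 of 22 at both (8050, highest other 16328, and 7804, highest other 14117). The larger splits follow a structure of the samples. Every other split as large kept the libraries of a species together in at least 1 stage, and splits that mixed the species in both stages called at most 3 genes.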

How the results depend on the processing

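The set test alternatives, the 4-fold preference and thinning were chosen after the data were seen. All 894 alternative values of the 58 named gene contrasts kept their sign and their call. Counts of called genes stayed within 1.5 times the reported count with DESeq2, RLE size factors, no low-count filter, removal of genes at 0 in a species, thinning and each library left out, which gave 8662 to 10101 for the least deep comparison, C. rubella against C. grandiflora seedlings. With RLE size factors the expanding bud genes called the same way in both selfing species were 3379 higher and 5028 lower (4032 and 4349 with TMM), and in dividing buds C. orientalis had 6235 higher and 7370 lower (6975 and 6784 with TMM). No scaling shifted the median gene of a contrast by over 0.1 log2. Replicate numbers did not pair the samples: same-numbered pairs had a median correlation of -0.00484, 2 were over 0.1, and 7 of 27 libraries correlated best with their own number. The replicate block moved the expanding bud count of C. rubella against C. grandiflora from 13830 to 13811 and changed 0 of 45 set calls. The planned tests of named gene lists were not run, because no identifier could be matched to a name.

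Requiring a log2 fold of at least 1 lowered every count, by its construction. In expanding buds the counts became 4716 (C. rubella against C. grandiflora), 5667 (C. orientalis against C. rubella) and 6345 (C. orientalis against C. grandiflora), in dividing buds 4899, 5799 and 5586, and in seedlings 3444, 5824 and 5043. Expanding against dividing buds gave 7947, 6109 and 5625 and dividing buds against seedlings 10025, 10003 and 9636 in C. grandiflora, C. rubella and C. orientalis. The interactions gave 2259 and 3001 for C. rubella and 3071 and 3614 for C. orientalis, and same-way genes 2172, 2150 and 1308. An adjusted p under 0.01 gave interaction counts of 3086, 4720 and 5208 and 2600 same-way genes in seedlings. With the compared groups alone, 5861 genes were called for C. rubella against C. grandiflora seedlings and 2514 same-way in seedlings, and the cause was not tested. Of 45 set tests 12 were called, 5 with an estimated correlation and 31 by fry, which asks another question. A 4-fold preference selects fewer genes and gave shares of 12.3%, 6.70% and 7.25% in expanding buds and 2.61%, 0.923% and 1.04% in dividing buds for C. grandiflora, C. rubella and C. orientalis, in the same order as before except that C. orientalis lay above C. rubella in dividing buds. The larger direction of near-even counts also turned in some stage contrasts and interactions, so their balance carries no weight.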

Other observations

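The most abundant genes of C. grandiflora expanding buds took a larger part of the counts than those of the selfing species. The 10 most abundant genes of a library took 4.55% ± 0.0621 of gene counts in C. grandiflora expanding buds, 2.78% ± 0.0489 in C. rubella and 3.10% ± 0.139 in C. orientalis (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Of the 10 genes with the highest mean in C. grandiflora, singled out after their values were seen, 9 were called lower in C. rubella and 8 of those in C. orientalis. The exception, Carubv10018993m.g, had a log2 fold of -0.36 in C. orientalis (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.345). Carubv10021016m.g was higher in both, with log2 folds of 0.49 and 0.53. Genes picked for a high mean in a species tend to be lower in another, and of the 10 most abundant genes of C. orientalis 7 were called lower and 3 higher in C. grandiflora, and of those of C. rubella 4 lower and 3 higher. In dividing buds and seedlings C. grandiflora had the lowest share instead of the highest, with 2.60% ± 0.0751 and 5.34% ± 0.672 against 2.82% ± 0.0921 and 6.26% ± 0.249 in C. rubella and 3.03% ± 0.107 and 7.10% ± 0.175 in C. orientalis.

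Fewer genes were detected in C. orientalis than in C. grandiflora at every stage. Reads that differ in sequence from the single set of gene models can be lost, so an undetected gene need not lack transcripts. With every library thinned to the same depth, 22253 ± 75.3 genes had a count in C. grandiflora expanding buds, 22181 ± 81.9 in C. rubella and 21571 ± 47.4 in C. orientalis. In dividing buds the numbers were 22318 ± 73.7, 21656 ± 142 and 21654 ± 16.2, and in seedlings 21660 ± 213, 21047 ± 66.02 and 20823 ± 73.9 (SD, n = 3 each).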
